A study of Mus musculus with 12 samples.

How the data were processed

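Polyadenylated RNA was sequenced from whole kidneys and from F4/80+ cells of separate kidneys, per the labels, in 4 groups of 3 biological replicates. Genotype, sample type and replicate were taken from the labels, and every library was matched to its count column by the short name in its title. The submitters' processing notes named STAR, DRAGEN, DESeq2 and the genome build mm10, without versions, roles or order, and the annotation release was not given in the sources used here. The coordinates in the tables matched the mm10 annotation used here, in which 15356 of the 15361 kidney identifiers and 18124 of the 18145 F4/80+ identifiers were found once version suffixes were left off.

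The authors provided a table per sample type. Each deposited table held raw counts per gene and library, which were whole numbers with library totals that differed between samples. The kidney table held 15361 genes, all protein coding, with a row sum of at least 12, and the F4/80+ table held 18145 genes of 22 biotypes, 13858 of them protein coding, with a row sum of at least 10. The deposited log2 fold change was Arg/Arg over Trp/Trp in kidney and Trp/Trp over Arg/Arg in F4/80+ cells, by its sign against the counts, and was turned to Trp/Trp over Arg/Arg throughout. The deposited ratio was 2 to the power of that log2 value. The deposited p-value and adjusted p-value, the score columns (the SE and the Wald statistic) and the signal column (the mean of counts divided by size factors) were those DESeq2 writes. An adjusted p was present for 14556 genes in kidney and 5431 in F4/80+ cells in the authors' deposited tables. The reason for missing values was not given in the sources used here.

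Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Each table was fitted on its own with genotype as the only term. Genes were kept by filterByExpr (minimum count 10 in at least 3 libraries, minimum total count 15), libraries were scaled by TMM, and genotypes were compared with the edgeR quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of an edgeR log2 fold change was its absolute value divided by the square root of the F statistic of that test. It therefore restates the test and is no separate measure of spread. Gene lists fixed in advance, 36 in number, were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists with at least 5 tested members. camera with an estimated correlation and fry were run beside it. fry tests whether the genes of a list move, on balance, in a direction, and does not compare them with other genes. For each list, members were also adjusted over the list alone. The overlap of the tables was tested with Fisher's exact test, one-sided. The difference of genotype effects between sample types was fitted in edgeR as an interaction over all 12 libraries. Sample types were compared on CPM over nuclear protein-coding genes held by both tables, by the mean log2 level of each list, with an exact permutation test of 6 against 6 libraries, two-sided, adjusted over 33 lists.

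The tests, filters, thresholds, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to be later. The rule named Sh2b3, the 12 largest changes in each direction among genes that passed, or, with fewer than 10 passing, the 10 genes of smallest unadjusted p with a mean count of at least 50, and up to 4 members of smallest p from each described list. Predicted genes without a name and pseudogenes were left out of it. The interaction of genotype with sample type for single genes was set down in advance, to be fitted if both tables held raw counts. Its list test, the comparison of sample types, the leave-one-out fits of DESeq2, of the overlap and of the interaction, and the removal of mitochondrial genes were added after seeing the data.

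Total counts ranged from 19.6 to 54.7 M per kidney library and from 35.9 to 51.6 M per F4/80+ library. The spread between replicates, as the common biological coefficient of variation in edgeR, was 0.101 in kidney and 0.28 in F4/80+ cells. The procedure was tested on simulated data with known changes at this depth and spread. In kidney, edgeR recovered 62.7% of genes changed by 1.5-fold, 85.1% by 2-fold and 97.0% by 4-fold. In F4/80+ cells it recovered 0%, 17.9% and 71.2%. The interaction test recovered 84% of genes that differed by 4-fold, but its simulation gave each gene the same spread in both sample types. That share therefore does not show the recovery at the wider spread of F4/80+ cells. A list shifted by 0.5 log2 units was called in 20 of 20 simulations in kidney and in 12 of 20 in F4/80+ cells. Genes were simulated independently of each other, unlike those of some real lists. The estimated correlation of MHC class II genes was 0.73 in kidney and 0.49 in F4/80+ cells. The list simulations therefore do not show how often camera with the preset correlation passes lists whose genes move together. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1, so genes were tested only by models that pool the spread over genes.

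List tests without a library kept the genes tested with all libraries where they stand beside a list, and filtered the genes anew in the count of alternatives. The alternatives were DESeq2 size factors, the DESeq2 test, no filter, a filter on a mean count of at least 100, a threshold of 0.1, the replicate number as a block, each library left out in turn, the adjusted p of the authors' deposited table, and the set tests above. Other splits of the libraries into groups of 3 were fitted for every count of genes or lists. The list of sex-linked transcripts (Xist, Tsix and 4 Y-linked genes) was used only to check samples and had too few measured members for a list test, while other X-linked genes were tested like any gene.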

Results

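The data were counts from RNA sequencing, labelled as of polyadenylated transcripts, in mice edited with CRISPR-Cas9 to carry 2 copies of either allele of a coding polymorphism in Sh2b3. Sh2b3 encodes LNK, an adaptor protein that restrains cytokine signalling in blood cells. The alleles were named Arg and Trp, and tissue was taken after 4 weeks of angiotensin II, a peptide hormone that raises blood pressure. The 12 libraries formed 4 groups of 3 biological replicates, namely whole kidney from Arg/Arg mice, whole kidney from Trp/Trp mice, and F4/80+ cells from separate kidneys of each genotype. F4/80, the product of Adgre1, is a surface protein of mouse macrophages, and the cells were taken from a Percoll gradient with anti-F4/80 microbeads. No library came from mice without angiotensin II.

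Arg/Arg kidney replicates 1, 2 and 3 held 34.6, 54.7 and 32.7 M counts (M for mega), and Trp/Trp kidney replicates 1, 2 and 3 held 37.5, 46.3 and 19.6 M. Arg/Arg F4/80+ replicates 1, 2 and 3 held 44.5, 35.9 and 51.6 M counts, and Trp/Trp F4/80+ replicates 1, 2 and 3 held 39.0, 51.1 and 49.1 M. Mitochondrially encoded transcripts took 7.9 to 9.4% of the counts in kidney libraries. In the F4/80+ libraries they took 70.1 to 83.6%, of which the mitochondrial ribosomal RNAs, absent from the kidney table, made up 50.8 to 68.5% of all counts. The kidney table held protein-coding genes only, so its share leaves out these RNAs and the ranges are unlike measures. Nuclear protein-coding genes were left with 17.8 to 50 M counts in kidney libraries and 6.9 to 11.1 M in F4/80+ libraries. Levels are given as CPM, the count scaled to a common library size, as mean ± SD with n = 3, and log2 fold changes as Trp/Trp over Arg/Arg ± SE. Within a sample type that size included the mitochondrial counts. CPM in F4/80+ cells are therefore not comparable with CPM in kidney, except where given over nuclear protein-coding genes.

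The first comparison asked which transcripts differed between Trp/Trp and Arg/Arg kidneys under angiotensin II. Marker genes of resident macrophages, dendritic cells, and T and NK cells rose in Trp/Trp kidneys as groups by the list test camera, with median log2 fold changes of 0.54, 0.57 and 1.00, which were 0.25, 0.24 and 0.27 without Trp/Trp replicate 1. Genes of MHC class II antigen presentation, which display peptides to helper T cells, also rose as a group, with a median of 0.54 (0.28 without that library), although each of these 4 lists had an adjusted p of 0.65 with an estimated correlation. Cx3cr1, the fractalkine receptor of monocytes and macrophages, was at 2.56 ± 0.282 CPM in Arg/Arg kidneys and 5.96 ± 1.17 in Trp/Trp kidneys (SD, n = 3). Mpeg1, which encodes the pore-forming protein perforin-2 of macrophages, was at 16.1 ± 1.13 and 28.9 ± 7.56 (SD, n = 3). Genes of fatty acid oxidation and the peroxisome fell as a group, with a median of -0.07 (adjusted p = 0.65 with an estimated correlation, and 0.09 without Trp/Trp replicate 1 at the preset correlation). Their member Ehhadh, a peroxisomal enzyme of that pathway, was at 918 ± 39.9 in Arg/Arg and 750 ± 31.2 in Trp/Trp kidneys (SD, n = 3).

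No single gene passed the test in kidney. edgeR called 0 of 14464 genes, with a smallest adjusted p of 0.843, while 826 genes had an unadjusted p under 0.05 (532 higher, 294 lower in Trp/Trp) where 723 are expected if no gene differs and genes are independent, and the 9 other splits of the 6 libraries gave 310 to 1142, 2 of them more than the real one. DESeq2 called 15 genes, 10 higher and 5 lower, and the authors' deposited table held the same numbers of calls. The DESeq2 count was 1 without Arg/Arg replicate 2, 40 without Arg/Arg replicate 3 and 51 without Trp/Trp replicate 2. The count at an unadjusted p under 0.05 was 492 without Arg/Arg replicate 2 and 1254 without Trp/Trp replicate 2. The genotypes' libraries did not overlap for 1611 genes, or 11.1%, where chance gives 10%.

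Sh2b3 itself (ENSMUSG00000042594.16, chromosome 5, 121815488 to 121837646 in mm10) was at 32.8 ± 4.10 CPM in Arg/Arg and 36.2 ± 1.60 in Trp/Trp kidneys (SD, n = 3), a log2 fold change of 0.14 ± 0.09 that did not pass in edgeR (adjusted p = 0.848). It was 0.05 without Arg/Arg replicate 1 and 0.22 without Arg/Arg replicate 3. The 10 genes of smallest p in kidney shared an edgeR adjusted p of 0.843 and are given as values. Cx3cr1 (ENSMUSG00000052336.7, chromosome 9, 119901616 to 120069879) had a log2 fold change of 1.22 ± 0.19. Plek, which encodes the platelet and leukocyte protein pleckstrin, had 1.05 ± 0.18, and Il2rb, a cytokine receptor chain of T and NK cells, had 1.17 ± 0.23. Mpeg1 (ENSMUSG00000046805.10, chromosome 19, 12460779 to 12465283) had 0.84 ± 0.17, and Ucp1, the uncoupling protein of brown fat, had 1.69 ± 0.35 at 0.745 CPM in Arg/Arg kidneys. Dusp1, a phosphatase that switches off MAP kinases, was at 63.7 ± 5.80 in Arg/Arg and 92.0 ± 10.3 in Trp/Trp kidneys (SD, n = 3). Cyp24a1, the kidney enzyme that inactivates vitamin D, was at 112 ± 22.2 and 170 ± 2.53 (SD, n = 3). Nt5e, the ectoenzyme CD73 that makes adenosine, was at 148 ± 17.5 and 99.7 ± 15.4 (SD, n = 3). Rin3 had a log2 fold change of 0.31 ± 0.07 and Ehhadh (ENSMUSG00000022853.7, chromosome 16, 21761287 to 21787807) of -0.29 ± 0.06. Outside this choice, and picked after their values were seen, the DESeq2 calls also held Hmcn2, Dbp and Cd52 among the higher genes and Bcat1, Nr1h4 and H1f2 among the lower genes.

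**Figure D1:**
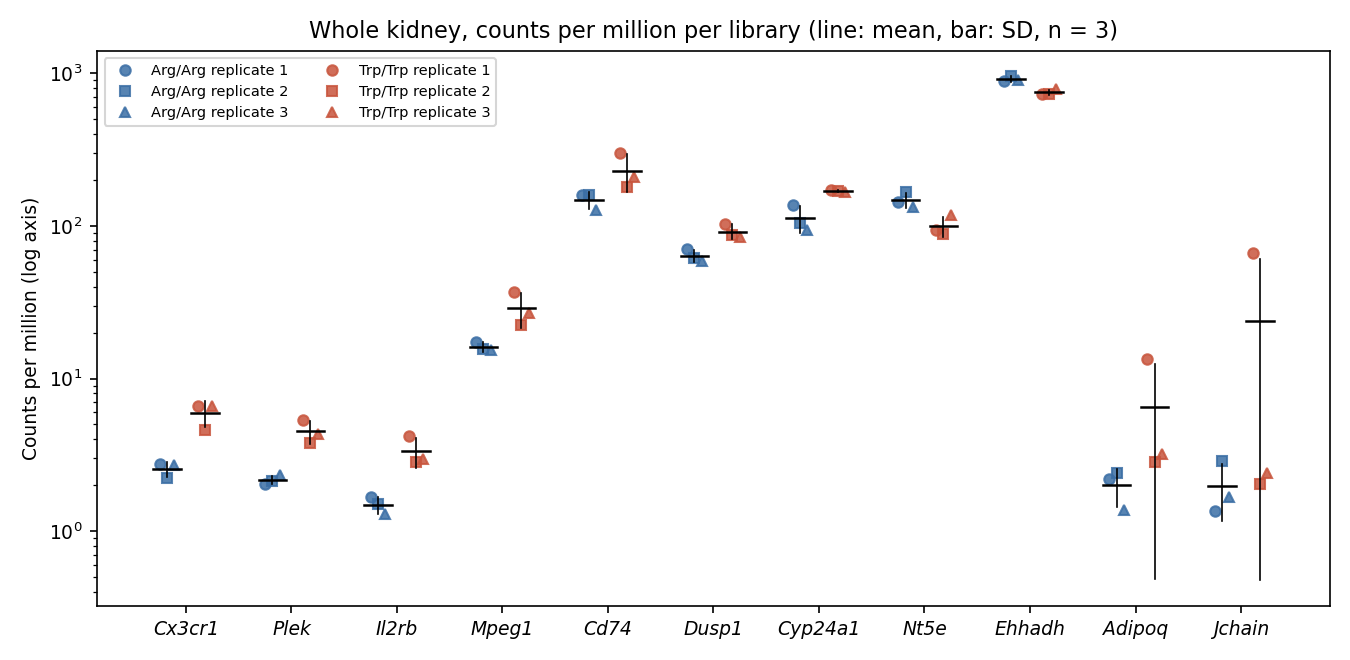
CPM on a log axis for 11 genes in the 6 whole kidney libraries, with a point per library (blue Arg/Arg, red Trp/Trp; the shape gives the replicate), a line at the mean and a bar for the SD (n = 3). Cx3cr1 sits at 2.24 to 2.75 in Arg/Arg and at 4.61 to 6.65 in Trp/Trp kidneys, while Jchain and Adipoq are at 66.8 and 13.4 in Trp/Trp replicate 1 and at 2.03 to 3.18 in Trp/Trp replicates 2 and 3.

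Of the 35 lists tested in kidney by camera with a preset correlation, 18 rose and 4 fell in Trp/Trp mice. None passed with an estimated correlation, where the adjusted p was 0.65 for each of the 6 lists named next, and none with fry, whose smallest adjusted p was 0.51. Among 20 resident macrophage markers, 7 rose when adjusted over the list alone and 0 when adjusted over all genes (camera adjusted p = 4.2e-07). Lyz2, a lysozyme of myeloid cells, was at 13.2 ± 2.23 in Arg/Arg and 29.1 ± 14.95 in Trp/Trp kidneys (SD, n = 3), and Adgre1 at 4.43 ± 0.940 and 6.93 ± 0.810. Of 12 MHC class II genes, 7 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 2.7e-06), among them the invariant chain Cd74, at 149 ± 18.9 and 231 ± 64.1 (SD, n = 3). Of 16 dendritic cell markers, 5 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 2.7e-06), with Wdfy4 at a log2 fold change of 1.01 ± 0.26 and Xcr1 at 1.01 ± 0.30. Of 19 T and NK cell markers, 1 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 4.2e-07), and 18 had a positive log2 fold change, with Cd3d at 1.54 ± 0.33 and Cd8a at 0.82 ± 0.23. Among 25 complement and lysosome genes of phagocytes, 0 rose either way and 21 had a positive value (camera adjusted p = 0.00014), with C1qb at 0.56 ± 0.16 and Fcgr3 at 0.57 ± 0.16. Perirenal fat markers rose as well (camera adjusted p = 0.00076), 2 of 13 when adjusted over the list alone and 0 over all genes, with Adipoq at 2.00 ± 0.549 in Arg/Arg and 6.47 ± 5.99 in Trp/Trp kidneys (SD, n = 3). These 6 lists passed without each library in turn, but without Trp/Trp replicate 1 the medians of all but the complement and lysosome list, which stayed at 0.06 (0.10 without Arg/Arg replicate 3), were 0.17 for fat markers and 0.24 to 0.28 for the others.

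The other 16 lists that passed in kidney no longer passed without Trp/Trp replicate 1. That library stood apart on the first principal component, which held 40.7% of the variance, at 39.6 where the other 5 libraries lay between -12.9 and -3.9. Fibrosis and extracellular matrix genes rose by camera, with a median of 0.31 and 30 of 32 members positive (adjusted p = 6.3e-06, 0.45 without that library, and 0.65 with an estimated correlation). Their member Bgn, a matrix proteoglycan, was at 155 ± 10.9 in Arg/Arg and 207 ± 38.7 in Trp/Trp kidneys (SD, n = 3), and Dcn was at 109 in Trp/Trp replicate 1 and at 39.5 and 40.0 in Trp/Trp replicates 2 and 3. Markers of fibroblasts, pericytes and smooth muscle rose with a median of 0.31 (adjusted p = 0.0001, 0.71 without that library, and 0.65 with an estimated correlation), among them Des at 0.38 ± 0.11 and Pdgfrb at 0.29 ± 0.11. Kidney injury markers rose with the same median (adjusted p = 0.0034, 0.31 without that library, and 0.65 with an estimated correlation), although the cell cycle inhibitor Cdkn1a in that list had a log2 fold change of -0.44 ± 0.16. Without that library the medians of these 3 lists were 0.03, 0.02 and 0.05. B and plasma cell markers rose with a median of 1.32 (adjusted p = 0.024, 0.68 with an estimated correlation), which was 0.02 without that library (adjusted p = 0.62), and also did not pass without Arg/Arg replicate 3 (adjusted p = 0.23). Jchain, the joining chain of secreted antibodies, was at 66.8 in Trp/Trp replicate 1 and at 1.35 to 2.87 in the other 5 libraries. Fatty acid oxidation genes fell, 2 of 31 when adjusted over the list alone and 0 over all genes (camera adjusted p = 3.5e-05, 0.09 without that library, and 0.65 with an estimated correlation), with Pex11a at -0.32 ± 0.08 and a median of -0.14 without Trp/Trp replicate 3. For these 5 lists and the other 11, 0 members passed when adjusted over all genes.

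**Figure D2:**
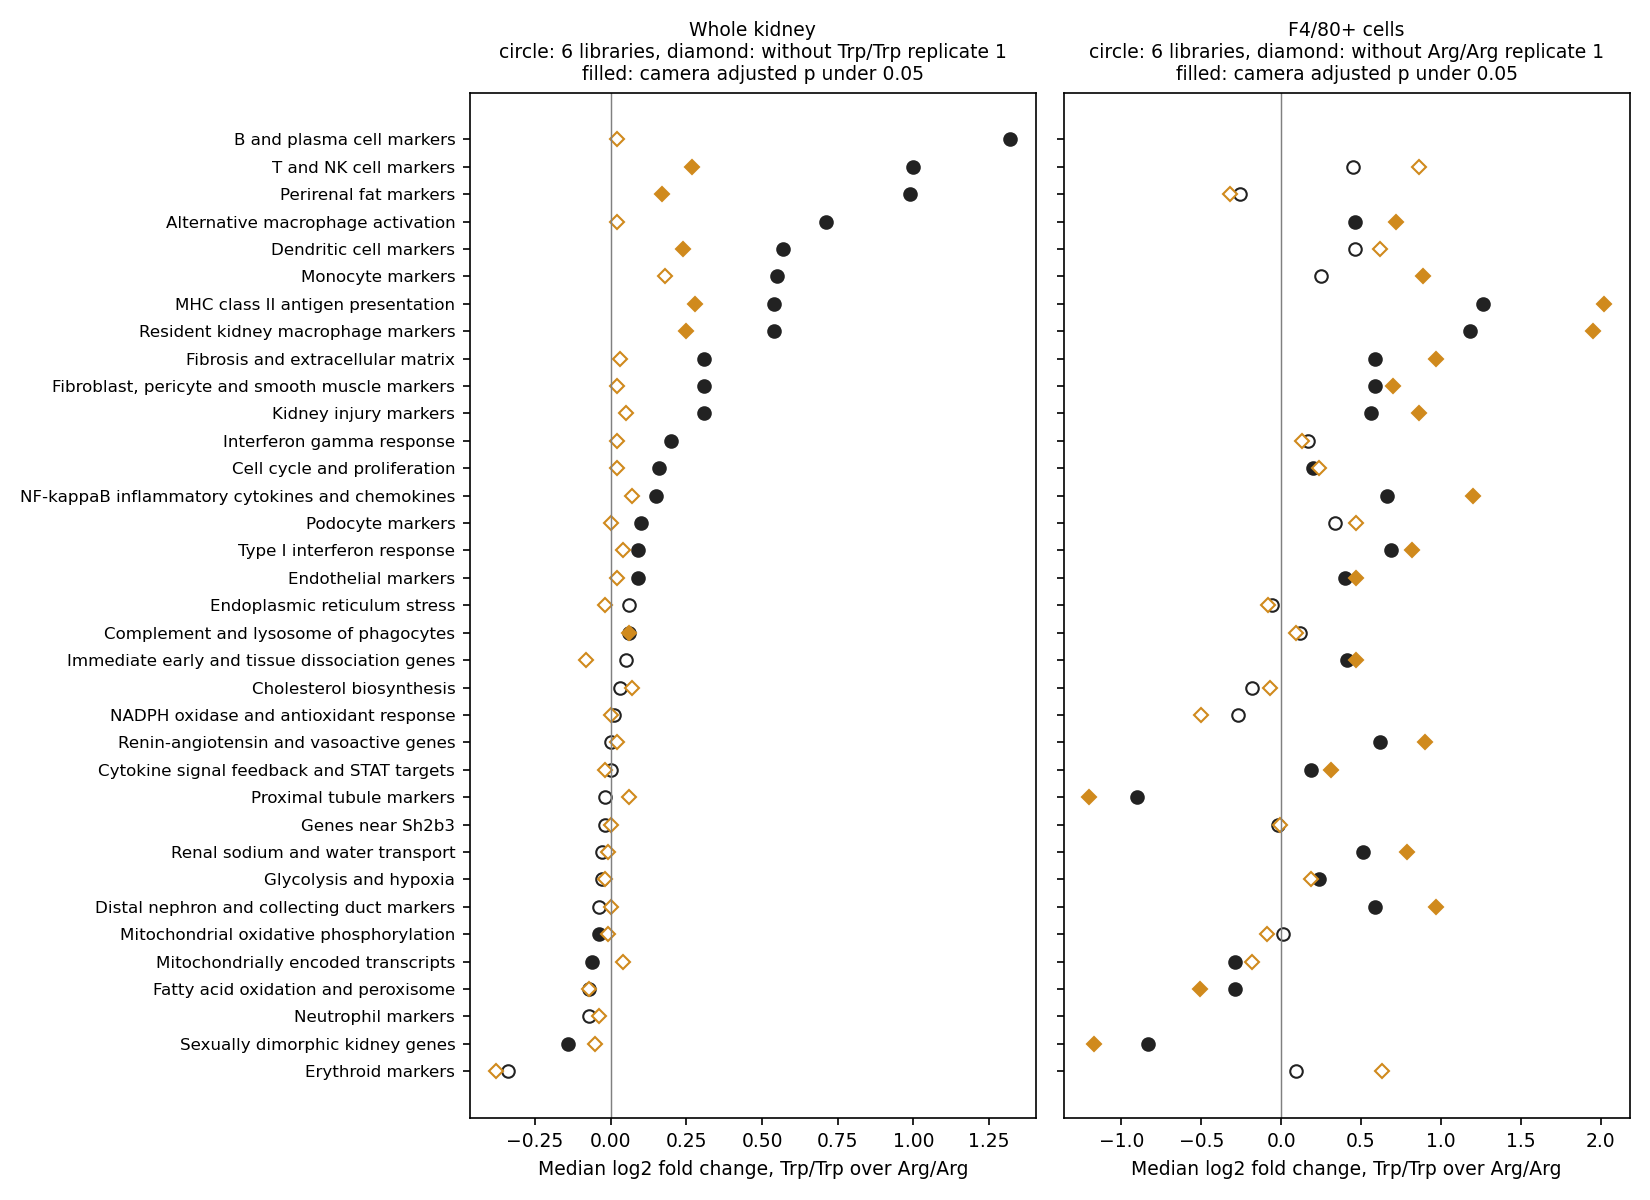
Median log2 fold change of Trp/Trp over Arg/Arg for each gene list tested in whole kidney (left) and F4/80+ cells (right), with circles for the 6 libraries and diamonds for the 5 libraries without Trp/Trp kidney replicate 1 or without Arg/Arg F4/80+ replicate 1; filled symbols passed camera with the preset correlation. Proximal tubule markers lie at -0.90 in F4/80+ cells and near 0 in kidney, and the fibrosis median in kidney, 0.31 with all libraries, lies near 0 without Trp/Trp replicate 1.

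The second comparison asked which transcripts differed between genotypes in the F4/80+ cells. That name follows the labels, since Adgre1 was at 1.26 to 16.7 CPM over nuclear protein-coding counts in these libraries and at 4.12 to 8.33 in whole kidney, so the changes are those of the preparations and need not lie in macrophages. Resident macrophage markers and MHC class II genes rose as groups in Trp/Trp F4/80+ libraries, with median log2 fold changes of 1.18 and 1.26 by camera (adjusted p = 0.32 with an estimated correlation for both), which were 1.95 and 2.02 without Arg/Arg replicate 1. Proximal tubule markers fell, with a median of -0.90 and a negative value in all 24 members, while distal nephron and collecting duct markers rose with a median of 0.59 (adjusted p = 0.32 with an estimated correlation for both). H2-Ab1, an MHC class II chain, was at 7.36 ± 2.60 CPM in Arg/Arg and 17.5 ± 1.15 in Trp/Trp cells (SD, n = 3). Slc5a12, a lactate transporter of the proximal tubule, was at 43.1 ± 22.9 and 12.4 ± 4.19 (SD, n = 3). The cytokine gene Il1b was at 3.78 ± 2.95 and 13.5 ± 5.80 (SD, n = 3) and belonged to a list of inflammatory cytokines and chemokines that rose with a median of 0.66 (adjusted p = 0.32 with an estimated correlation). Immediate early and tissue dissociation genes rose as well, with a median of 0.41 (camera adjusted p = 0.002, 0.34 with an estimated correlation). Whether the isolation of the cells contributed to either rise was not tested.

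No single gene passed the test in F4/80+ cells either. edgeR called 0 of 15225 genes, with a smallest adjusted p of 0.605, while 1224 genes had an unadjusted p under 0.05 (674 higher, 550 lower) where 761 are expected in the same way, and the 9 other splits of the 6 libraries gave 70 to 3156, 3 of them more than the real one. DESeq2 called 4 genes, all lower, and the authors' deposited table held 20 calls, 3 higher and 17 lower, with an adjusted p for 5431 genes against 17088 in the DESeq2 fit. The DESeq2 count was 964 without Arg/Arg replicate 1, 122 without Trp/Trp replicate 1, 1 without Arg/Arg replicate 2 and 0 without Arg/Arg replicate 3. The count at an unadjusted p under 0.05 was 2788 without Arg/Arg replicate 1, 692 without Arg/Arg replicate 2, 364 without Arg/Arg replicate 3 and 811 without Trp/Trp replicate 3. On the first principal component, which held 44.1% of the variance, Arg/Arg replicate 1 lay at -24.1, beside Trp/Trp replicates 2 and 3 at -52.2 and -23.1 and away from Arg/Arg replicates 2 and 3 at 53.4 and 39.9. Trp/Trp replicate 1 lay between, at 6, and so apart from its own group. On the second component, which held 23.7%, Trp/Trp replicate 1 lay at 47.6 and Arg/Arg replicate 3 at -43.3. The other libraries lay between -12.5 and 12.7 there. The genotypes' libraries did not overlap for 1620 genes, or 10.6%, where chance gives 10%.

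Over nuclear protein-coding counts Sh2b3 was at 23.5 ± 4.54 CPM in F4/80+ libraries and 37.9 ± 3.95 in kidney (SD, n = 6). In the genotype comparison it was at 4.56 ± 0.631 CPM in Arg/Arg and 4.52 ± 1.52 in Trp/Trp F4/80+ cells (SD, n = 3), a log2 fold change of -0.01 ± 0.28. Its sign turned without Arg/Arg replicate 2 (0.08), without Trp/Trp replicate 2 (0.19) and without Trp/Trp replicate 3 (0.03). The 10 genes of smallest p had an edgeR adjusted p of 0.605 each. Clec2h (ENSMUSG00000030364.6, chromosome 6, 128662385 to 128677374) had a log2 fold change of -1.93 ± 0.32, and Cyp26b1 (ENSMUSG00000063415.12, chromosome 6, 84571414 to 84593908), which breaks down retinoic acid, of -2.36 ± 0.50. Slc5a12 (ENSMUSG00000041644.14, chromosome 2, 110597298 to 110647779) had -1.79 ± 0.38 and Car14 (ENSMUSG00000038526.14, chromosome 3, 95897768 to 95904691), a carbonic anhydrase, had -1.67 ± 0.37. These 4 were the DESeq2 calls. H2-Ab1 (ENSMUSG00000073421.6, chromosome 17, 34257689 to 34269419) had 1.25 ± 0.27, Sdf2l1 1.49 ± 0.33, Cnp 1.32 ± 0.32 and Lrrc32 1.27 ± 0.31. Pik3c2g had -1.07 ± 0.24 and Maf, which encodes a transcription factor, had -1.14 ± 0.28. The authors' deposited table called Clec2h, Slc5a12 and Car14 too, but not Cyp26b1. Its 3 higher calls were H2-Ab1, Cd74 and Il1b, with log2 fold changes of 1.22, 1.41 and 1.81 there. Its 17 lower calls also held the transporters Slc6a19 and Slc13a1 and the collectrin gene Cltrn, picked here after their values were seen. Their log2 fold changes there were -1.40, -1.18 and -1.26.

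**Figure D3:**
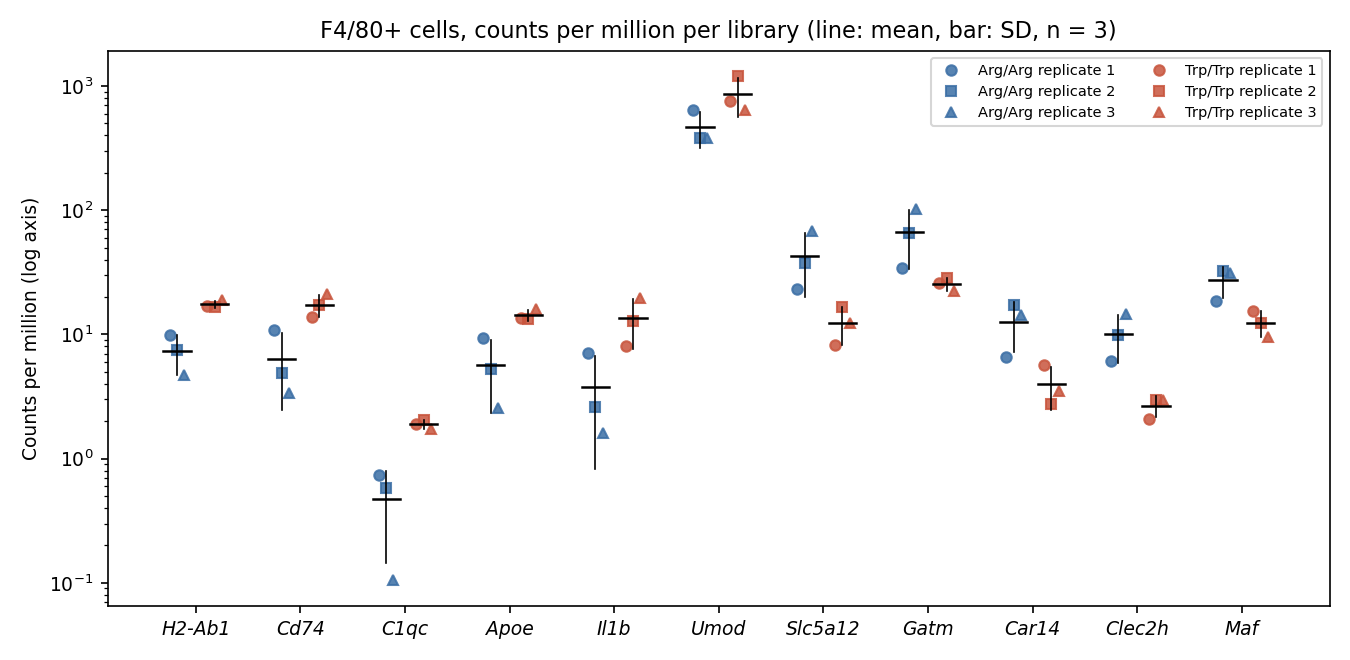
CPM on a log axis for 11 genes in the 6 F4/80+ libraries, with a point per library (blue Arg/Arg, red Trp/Trp; the shape gives the replicate), a line at the mean and a bar for the SD (n = 3). H2-Ab1 sits at 4.70 to 9.90 in Arg/Arg and 16.7 to 18.8 in Trp/Trp cells, and Gatm at 34.5 to 102 in Arg/Arg and 22.4 to 28.4 in Trp/Trp cells, with Arg/Arg replicate 1 nearest to Trp/Trp for both.

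Of the 33 lists tested in F4/80+ cells by camera with a preset correlation, 16 rose and 4 fell. None passed with an estimated correlation, where the adjusted p was 0.32 for each of the 7 lists named next, and none with fry, whose smallest adjusted p was 0.24. Of 24 proximal tubule markers, 3 fell when adjusted over the list alone and 0 over all genes (camera adjusted p = 4.1e-11), with Gatm, an enzyme of creatine synthesis, at 67.2 ± 33.6 in Arg/Arg and 25.5 ± 2.97 in Trp/Trp cells (SD, n = 3) and Cyp2e1 at 805 ± 400 and 374 ± 96.2. Of 21 distal nephron and collecting duct markers, 0 rose either way and 20 had a positive value (camera adjusted p = 2e-07), with Umod, the main urinary protein, at 467 ± 151 and 865 ± 301 (SD, n = 3). Of 16 resident macrophage markers, 3 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 9.4e-06), with Apoe at 5.71 ± 3.39 and 14.3 ± 1.40 (SD, n = 3) and the complement gene C1qc at a log2 fold change of 2.02 ± 0.52. Of 10 MHC class II genes, 6 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 1.5e-07), with Cd74 at 1.44 ± 0.37 and H2-Aa at 1.35 ± 0.43. Of 22 inflammatory cytokine and chemokine genes under NF-kappaB, 4 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 1e-07), with Il1b at 1.84 ± 0.49 and Tnf at 3.06 ± 0.74, where Tnf had no count in Arg/Arg replicate 2. Type I interferon response genes rose with a median of 0.69 and 21 of 24 members positive (camera adjusted p = 9.2e-07), with Ifitm3 at 0.90 ± 0.30, although 0 passed when adjusted over the list alone or over all genes. Fibrosis genes rose with a median of 0.59 and 23 of 25 members positive (camera adjusted p = 9.2e-07), with Col1a2 at 1.57 ± 0.48, and again 0 passed when adjusted over the list alone or over all genes. Tnf and Col1a2 were low, at 0 to 4.33 and 0.632 to 4.67 CPM over nuclear protein-coding counts, so their fold changes rest on few counts. These 7 lists passed without each library in turn. In mean log2 CPM, however, Arg/Arg replicate 1 lay near the Trp/Trp libraries. MHC class II genes were at 1.23 there and at 1.19 to 1.76 in Trp/Trp, with Arg/Arg replicates 2 and 3 at 0.12 and -0.07. Proximal tubule markers were at 7.14 there and at 6.45 to 7.62 in Trp/Trp, with Arg/Arg replicates 2 and 3 at 8.41 and 8.36. The differences of these lists thus rest mainly on Arg/Arg replicates 2 and 3. Without Arg/Arg replicate 1 the medians were 1.2 for the cytokine list and 0.97 for the distal nephron and fibrosis lists. The fibrosis median was 0.39 without Arg/Arg replicate 3. Immediate early and tissue dissociation genes rose in Trp/Trp cells as well, with a median of 0.41 and 24 of 28 members positive (camera adjusted p = 0.002, 0.34 with an estimated correlation), and passed without each library, with a median of 0.26 without Arg/Arg replicate 3. Of these, 0 passed when adjusted over the list alone or over all genes, and Ier3 had a log2 fold change of 0.68 ± 0.26. Mitochondrially encoded transcripts fell with a median of -0.29 (camera adjusted p = 0.0042, 0.41 with an estimated correlation), but did not pass without Arg/Arg replicate 1 (median -0.18, adjusted p = 0.19) or Trp/Trp replicate 1 (median -0.17, adjusted p = 0.37).

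The third comparison set the F4/80+ libraries against the kidney libraries over 13733 nuclear protein-coding genes held by both tables, with 6 libraries on each side and genes picked from the lists after their values were seen. Immediate early and tissue dissociation genes were higher in F4/80+ libraries by 3.12 in mean log2 CPM, and 27 of 28 members were higher there (exact permutation test, two-sided, adjusted p = 0.00509). Fos, a transcription factor induced within minutes of stimulation, was at 1.12 ± 0.360 CPM over these genes in kidney and 2560 ± 688 in F4/80+ libraries (SD, n = 6), and Egr1 was at 6.92 ± 2.52 and 1890 ± 455. Distal nephron and collecting duct markers were higher by 0.87 (exact permutation test, adjusted p = 0.00509), with Slc12a3, the thiazide-sensitive cotransporter, at 1760 ± 61.1 and 4440 ± 2050 (SD, n = 6). Resident macrophage markers differed by -0.54 (exact permutation test, adjusted p = 0.101), and 8 of 19 were higher in F4/80+ libraries, with Adgre1 at 6.24 ± 1.77 in kidney and 7.40 ± 6.45 in F4/80+ libraries and C1qa at 18 ± 5.40 and 2.80 ± 1.98 (SD, n = 6). Without Trp/Trp F4/80+ replicate 3 that difference was -0.66 and passed the threshold (exact permutation test, adjusted p = 0.0321; 0.0321 to 0.223 over all alternatives). Proximal tubule markers differed by -0.63 (exact permutation test, adjusted p = 0.0808), and 11 of 24 were higher in F4/80+ libraries, among them Lrp2, the receptor megalin, at 2510 ± 154 and 3380 ± 1590 (SD, n = 6). Inflammatory cytokine and chemokine genes were higher in F4/80+ libraries by 0.95, with 16 of 22 members higher (exact permutation test, adjusted p = 0.00953). Monocyte and dendritic cell markers differed by -0.46 and -0.57 (exact permutation test, adjusted p = 0.0264 and 0.00509). The smallest p that 6 against 6 libraries allow is 0.00216, and the sample types also differed in isolation and in the genes each table kept. The labels name polyadenylated RNA for both, which the share of mitochondrial ribosomal RNA leaves in doubt for the F4/80+ libraries, so a difference in library type stays open as well. The kidney table, with protein-coding genes only, cannot show that share for kidney libraries.

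**Figure D4:**
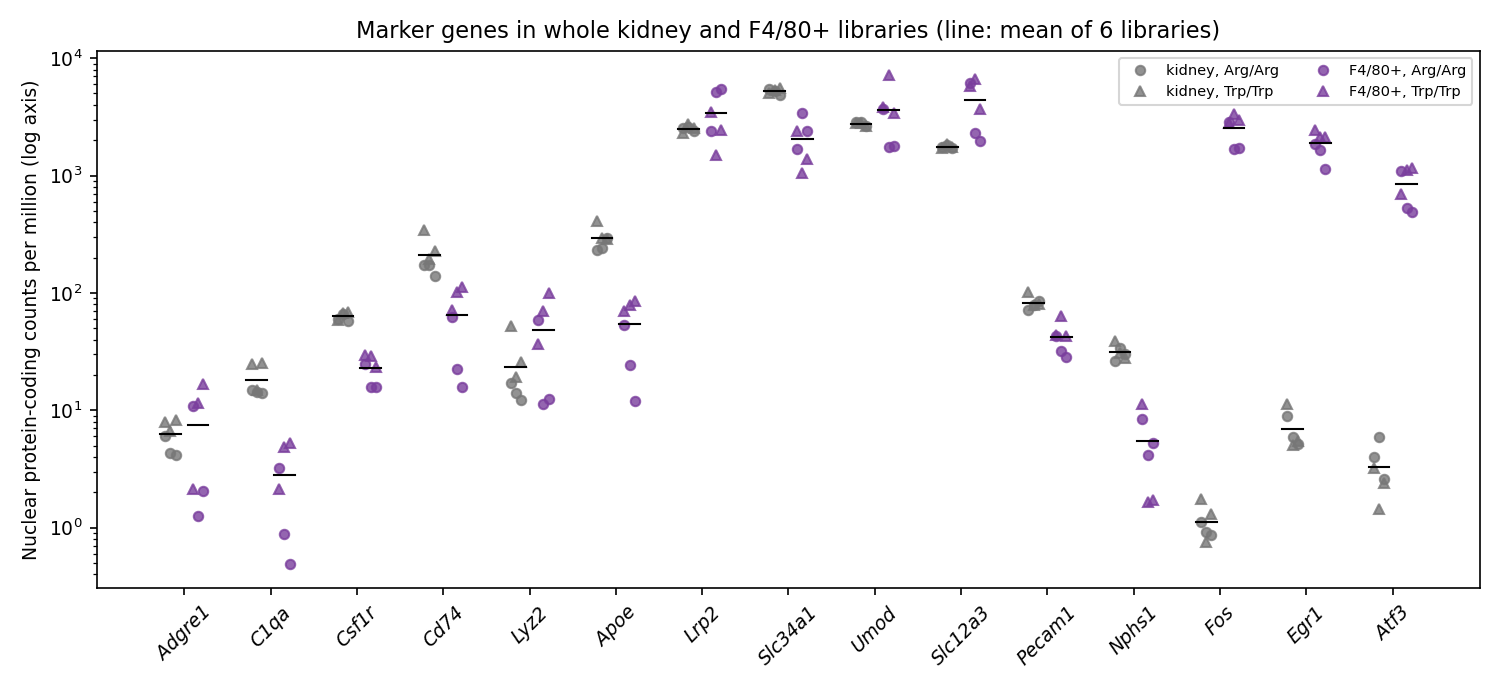
CPM over nuclear protein-coding counts, on a log axis, for marker genes in the 6 kidney (grey) and 6 F4/80+ (purple) libraries, with circles for Arg/Arg, triangles for Trp/Trp and a line at the mean. Of the macrophage genes drawn, Csf1r has means of 63.0 in kidney and 23.0 in F4/80+ libraries and Adgre1 of 6.24 and 7.40, while Fos, Egr1 and Atf3 are higher in every F4/80+ library.

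The fourth comparison asked whether the genotypes differed alike in kidney and in F4/80+ cells. With adjusted p the tables shared 0 genes, since edgeR called none in either, while at an unadjusted p under 0.05 they shared 69 genes higher in Trp/Trp and 22 lower. Of 12702 genes tested in both tables, chance would share 18.3 higher and 10.2 lower genes (Fisher's exact test, one-sided, p = 2.33e-22 and p = 0.000583), and 13 genes had opposite signs. Of the 69 shared higher genes, 20 belonged to the 13 fixed immune lists, among them Cd74 (0.63 ± 0.18 in kidney, 1.44 ± 0.37 in F4/80+ cells), H2-Eb1 (0.56 ± 0.16 and 1.34 ± 0.41) and the complement receptor gene C3ar1 (0.84 ± 0.26 and 1.52 ± 0.46). Acot12, an acetyl-CoA hydrolase, was among the lower genes, at -0.24 ± 0.09 and -0.86 ± 0.35. Across genes the log2 fold changes had a Pearson r of 0.28, although genes are not independent replicates. The 91 shared genes were 60, 53 and 156 without kidney libraries Arg/Arg 2, Trp/Trp 1 and Trp/Trp 2, and 185 and 37 without F4/80+ libraries Arg/Arg 1 and Arg/Arg 3. With libraries regrouped, 13 of the 200 pairs of splits of both tables, the real pair included, shared as many genes.

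Proximal tubule markers had a lower genotype effect in F4/80+ cells than in kidney by a median of -0.86 log2 units (interaction term, camera adjusted p = 1.7e-10, 0.78 with an estimated correlation). Distal nephron markers had a higher effect by 0.66 (2.3e-06, 0.48 with an estimated correlation) and type I interferon genes by 0.68 (9.1e-05, 0.48 with an estimated correlation), both as camera adjusted p. In all, 8 of 33 lists differed by camera, and 0 with an estimated correlation. The count of lists was 19 without Trp/Trp kidney replicate 1, 14 without Arg/Arg F4/80+ replicate 1 and 4 without Arg/Arg F4/80+ replicate 3. For single genes edgeR called 0 of 13507, with a smallest adjusted p of 0.694 and 926 genes at an unadjusted p under 0.05. It called 545 without Arg/Arg F4/80+ replicate 1 and 1 without Trp/Trp F4/80+ replicate 1. No other tool was run for the interaction of single genes.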

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

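The tests of single libraries, of fat, of tubule RNA, of whole-kidney RNA, of the makeup of the F4/80+ cells, of all pairs of splits for the overlap, and of drawn pairs of splits for the interaction as given here were chosen only after the result was seen, and the counts of other splits within a table were planned. The interaction of genotype with sample type drew attention to 8 lists, whose genotype effect differed between F4/80+ cells and kidney by camera. The median log2 difference was -0.86 for proximal tubule markers, 0.66 for distal nephron and collecting duct markers, 0.68 for type I interferon genes and 0.51 for renal sodium and water transport genes. It was -0.72 for sexually dimorphic kidney genes, 0.33 for inflammatory cytokines and chemokines, 0.63 for MHC class II genes and 0.21 for fibrosis genes. None of the 8 passed with an estimated correlation, where their adjusted p lay between 0.48 and 0.82.

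In Trp/Trp kidneys, 11 immune lists rose by camera, as did 7 other lists, and Trp/Trp replicate 1 stood apart from the other libraries. Without that library 5 of the 11 immune lists and 1 of the 7 other lists passed, and the resident macrophage median was 0.25 in place of 0.54, so how far this library alone sets the pattern stays open. Fat taken along with the kidney could bring leukocytes, and Adipoq and Plin1 reached 13.4 and 13.5 CPM in that library. The median excess over Arg/Arg in Trp/Trp replicates 2 and 3 was 0.17 of that in replicate 1 over 193 immune genes (95% bootstrap interval 0.12 to 0.26) and 0.05 (0.02 to 0.33) over the 13 tested genes of the fixed fat list, all of them also detected in Arg/Arg kidneys, so fat stays open too (5 adipocyte genes picked after their values were seen gave 0.09, 0.02 to 0.11). The bootstrap drew genes, which are not independent, so its intervals do not measure the spread between animals. A larger share of leukocytes in Trp/Trp kidneys, or more of these transcripts per cell, stays a hypothesis that was not tested, and no list passed with an estimated correlation (smallest adjusted p = 0.65).

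The F4/80+ libraries held resident macrophage markers at no more than the level of whole kidney (median log2 ratio -0.25 over 19 genes). RNA of tubule cells in the preparations may be the source of many counts, since 45 nephron markers from lists fixed in advance had a median log2 ratio of 0.42 to kidney (-0.49 for the 24 proximal and 1.19 for the 21 distal ones), with Kap at 15700 and Umod at 3600 CPM over nuclear protein-coding counts, although the F4/80 microbeads would remove tubule cells. RNA of undissociated whole kidney under these labels is argued against, since the immediate early list had a median log2 ratio of 2.79, and Fos was at 1.12 in kidney and 2560 in F4/80+ libraries. That list holds tissue dissociation genes, so it cannot tell enriched cells from dispersed kidney cells without enrichment. Whether the tubule RNA came from whole cells, debris or doublets was not tested. No biological explanation was tested for this pattern, as the design holds no other sorted cells.

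In Trp/Trp F4/80+ cells macrophage markers rose and proximal tubule markers fell, and distal nephron markers rose as well, by camera at the preset correlation only (adjusted p = 0.32 for each with an estimated correlation). A smaller share of proximal tubule RNA alone would raise macrophage and distal markers alike, and their mean log2 levels differed between genotypes by 0.38 (SE 0.18). That lies just beyond 2 SE, but the libraries overlapped (Arg/Arg -3.79, -3.99 and -4.26, Trp/Trp -3.84, -3.64 and -3.43), and the condition that they must not overlap was added after the value was seen. A change of makeup and a change within macrophages therefore cannot be told apart for these lists, with 3 libraries on each side. A genotype effect on the macrophages stays open and was not tested.

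With 6 libraries in a table, 10 splits into 3 and 3 are too few for a share under 0.05. In kidney, edgeR called 0 genes for the real split and at most 0 for the others, with 10 of the 10 splits calling as many, and 826 genes had an unadjusted p under 0.05 in the real split (310 to 1142 in the others). In F4/80+ cells it called 0 for the real split, with 1224 genes at an unadjusted p under 0.05 (70 to 3156 in the others), and 725 for the highest other, so that all 10 splits called as many. With a real count of 0, these shares of edgeR calls were fixed in advance in both tables and test nothing. The real split passed 22 lists in kidney (highest other 19, 1 of 10 splits as many) and 20 in F4/80+ cells (highest other 21, 2 of 10 splits as many). DESeq2 called 15 genes in kidney (highest other 27, 3 of 10 splits as many) and 4 in F4/80+ cells (highest other 1394, 4 of 10 splits as many). The F4/80+ split with 725 edgeR and 1394 DESeq2 calls set Arg/Arg replicate 1 with Trp/Trp replicates 2 and 3 against the other 3 libraries, which points to a structure of these samples other than genotype.

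The 91 genes shared by both tables in direction at an unadjusted p under 0.05 were matched or exceeded in 13 of all 200 pairs of splits, the real pair included (highest other 285), so chance is not excluded. The planned procedure draws 100 pairs when there are more, and that draw gave 4 of 100 (highest other 131), which taken alone would fall under 0.05. The full count was preferred with both results known, because it holds every pair and the draw is a sample of it. For the interaction, 100 of 100 drawn pairs gave as many genes as the real 0 (highest other 778), which a real count of 0 fixes in advance. At an unadjusted p under 0.05 the real pair had 926 genes (116 to 3223 in the others), and 42 of 100 drawn pairs had as many. For the 8 interaction lists it was 54 of 100 (highest other 24), so chance is not excluded for them, and the interaction draws were raised from 20 to 100, and the count for lists added, after a first count for genes.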

How the results depend on the processing

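The list test of the interaction, the leave-one-out fits of DESeq2, of the overlap, of the interaction and of the sample types, and the removal of mitochondrial genes, were chosen after seeing the data. The genes counted here were those named in the text, mostly for a small p, and the lists were those that passed. Both were thus chosen on the same libraries, so a kept direction was likely in advance and is no independent support. Of 1893 values of single genes other than Sh2b3 and of lists under alternatives, 1891 kept their direction in the test. The others were endothelial markers in kidney without Arg/Arg replicate 1 (median 0.01, range 0.01 to 0.14 without each library) and B cell markers in kidney without Trp/Trp replicate 1 (0.02, range 0.02 to 1.6), both reversed in the set test, and the median of mitochondrially encoded transcripts in kidney was 0.04 without Trp/Trp replicate 1, although its test kept its direction. Of 22 kidney lists, 77 of 242 values kept their direction but no longer passed, beside the 2 reversed ones. Of 20 F4/80+ lists, 59 of 239 values no longer passed.

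The edgeR count of 0 became 15 in kidney and 4 in F4/80+ cells with DESeq2, and 15 and 20 in the authors' deposited table, where fewer F4/80+ genes were adjusted over. The cause of the difference between edgeR and DESeq2 was not tested. Lists passed numbered 0 in both tables with an estimated correlation and with fry, and 0 for the interaction with an estimated correlation, which allows for genes that move together. With each library left out, 6 to 21 lists passed in kidney and 16 to 22 in F4/80+ cells, and DESeq2 called 1 to 51 and 0 to 964 genes. Sh2b3 in F4/80+ cells, at -0.01 in the reported fit, was reversed at 0.0018 with a mean count of at least 100, and was -0.32 to 0.19 without each library, reversed without 3 of them. In kidney it was 0.05 to 0.22 without each library. The overlap of 0 genes was 91 at an unadjusted p, where 43 had a mean count of at least 100 (fewer genes tested), and 37 to 185 without each library. Interaction genes numbered 0 to 545 and interaction lists 4 to 19 without each library, and the macrophage marker difference between sample types was -0.66 to -0.36. Beyond the fewer samples, the cause was not tested.

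Replicate numbers did not pair the samples: residual correlations of same-numbered samples were -0.08, -0.02 and -0.01 in kidney and -0.31, -0.49 and 0.18 in F4/80+ cells. Samples of different replicate numbers had -0.12 to 0.11 in kidney and -0.15 to 0.48 in F4/80+ cells. The highest there was between Arg/Arg replicate 2 and Trp/Trp replicate 1, and a batch shared across replicate numbers was not tested. With the number as a block, edgeR called 0 genes in each table, and 20 and 21 lists passed. The pseudocount alternatives and the test on recovered reads were not run, since the values were raw counts. In F4/80+ cells, 6.9 to 11.1 M nuclear protein-coding counts and a wide replicate spread limit calls to large changes.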

Other observations

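The clock genes, chosen after their values were seen, are given as values. In kidney, Dbp, an output gene of the circadian clock, was at 14.2 ± 0.627 CPM in Arg/Arg and 25.2 ± 9.16 in Trp/Trp mice (SD, n = 3), a log2 fold change of 0.81 ± 0.21. The period genes Per2 and Per3 had log2 fold changes of 0.30 ± 0.10 and 0.36 ± 0.15, and the opposing activators Arntl and Npas2 had -0.39 ± 0.12 and -0.45 ± 0.17. Of 12 clock genes, 5 had an unadjusted p under 0.05 in kidney and 0 in F4/80+ cells, and none passed edgeR in either table, while DESeq2 called Dbp in kidney. The time of day of tissue collection was not in the labels.

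In F4/80+ cells, Slc4a4, the bicarbonate cotransporter of the proximal tubule, was at 427 ± 183 CPM in Arg/Arg and 210 ± 54.1 in Trp/Trp cells, and the water channel gene Aqp2 of the collecting duct was at 14.1 ± 4.68 and 27.6 ± 13.9 (SD, n = 3). Renal sodium and water transport genes rose as a group by camera (median 0.51, adjusted p = 0.0019, 0.32 with an estimated correlation), with 24 of 33 members positive and a median of 0.79 without Arg/Arg replicate 1. Sexually dimorphic kidney genes fell with a median of -0.83 (camera adjusted p = 2.3e-05, 0.32 with an estimated correlation; median -0.46 without Arg/Arg replicate 3), among them Slc22a28 at 42.6 ± 19.7 and 24.3 ± 5.15 (SD, n = 3). All 12 libraries held counts of Y-linked genes. The oxidase gene Nox4 was at 60.7 ± 28.8 in Arg/Arg and 26.4 ± 2.38 in Trp/Trp cells (SD, n = 3), within a list that did not pass (camera adjusted p = 0.14, and 0.045 without Trp/Trp replicate 1).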
